A study of Mus musculus with 18 samples.

How the data were processed

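The series holds RNA sequencing of mouse uterine horn from 18 samples of 10 animals. One table of the whole series was deposited, with counts per Ensembl gene for 18 libraries. STAR 2.6.1d, featureCounts, Subread 1.6.4 and DESeq2 1.30.0 and the builds GRCm38.p4 and mm10 are named, without role or order, in the submitters' processing notes. The deposited values are raw counts, as whole numbers whose totals differ between libraries show. The gene annotation, the strand setting and the treatment of reads with several alignments are not given in the sources used here, so genes that overlap, antisense genes and near-identical copies may share or lose reads. RNA was extracted with TRIzol and libraries were made by standard Illumina protocols, per the labels' protocols.

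Columns were tied to samples by name only. The column names hold a prefix of letters, a code per animal and L or R, 10 ending in L and 8 in R, as the labels have 10 left and 8 right horns. The labels name animals by letters. The prefix was not read as the animal's letter, since it differs between the left and right columns of a code and repeats between codes. Of the 10 codes 2 have a left horn alone, as have 2 untreated animals in the labels, so these 2 columns were placed in the group of untreated left horns, without knowing which is which animal. The other 16 columns were not used in any step, since only the order of columns or accessions could have placed them in a group. Their names pair the left and right horns of 8 animals, but a comparison of sides over these animals would mix injured and untreated horns and was not made. The group of untreated left horns has 4 samples in the labels, of which 2 are analysed here. They come from separate animals. As a check that they are not copies of 1 library, their counts were set against counting noise: the chi-square per gene was 53.9, or 26.9 if each fragment gave 2 counts, so both were kept. This says nothing of a difference between animals beyond that of any separate libraries.

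The design fixed before the data were examined held 9 comparisons by edgeR's quasi-likelihood test, a camera test of 30 gene lists and alternatives for each. None was run, because each needs a group whose columns were not placed. The rule for named genes asked for Ptgs1 and Ptgs2 in each comparison, and then for the 12 rising and 12 falling genes with the smallest adjusted p. Ptgs1 and Ptgs2 are given, and the rest of the rule has nothing to act on. The other genes were named after their values were seen. They are leading or functionally well-known members of the 30 lists, genes near the floor, and genes with large differences between the 2 animals. The gene lists themselves are as fixed.

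Gene IDs were matched to GENCODE M21 (GRCm38), the same assembly as mm10. Of 27998 IDs 27645 matched, and the other 353 held 0.0524% and 0.0546% of counts. By that annotation the table holds 21631 protein-coding, 3502 lincRNA and 2282 antisense genes, and 0 microRNA, 0 immunoglobulin constant or variable and 0 T cell receptor constant genes. CPM were computed with the total of each library. TPM were computed from the counts and the length of the union of a gene's annotated exons, which allows genes to be compared within a library but rests on an annotation that need not be the one used for counting. Coordinates are 1-based and from GENCODE M21.

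The libraries held 68178389 and 60588346 counts, with 19962 and 19735 genes at 1 count or more. The 50 highest genes held 13.4% and 13.9% of counts. Among genes with 1 to 20 counts, 69.6% (exact binomial 95% interval 68.1 to 71.0) in the deeper and 70.5% (69.1 to 72.0) in the shallower library had an even count, more than the share near 50% that independent counts would give, and the cause was not tested. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A count of 0 allows up to 3 counts, or 0.0440 and 0.0495 CPM, and 0.0880 and 0.0990 CPM if each fragment gave 2 counts.

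The spread between the animals was taken from edgeR 4.0.16 in R 4.3.3 over 14329 genes with a mean of at least 1 CPM, scaled by TMM factors of 1.004 and 0.996, as the common dispersion. Log2 differences used a prior count of 2. A list's median difference was set against 10000 random lists of the same size drawn from 20 classes of mean expression. The procedure was tested on simulated data with 14329 genes, a coefficient of variation of 0.15 and 200 genes changed 4-fold. It returned 0.148 for the unchanged genes, and all 200 changed genes exceeded 2-fold, as did 30 unchanged genes. The simulated genes were independent and followed the model that edgeR fits. The simulation thus checks the computation, and cannot show whether that model suits these counts. TPM of nuclear protein-coding genes with a count in both libraries were compared between ranges of length by their 90th percentile, with 1000 bootstrap resamples. Copies of mitochondrial genes were searched among the transcripts of GENCODE M21 with blastn 2.17.0. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.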

Results

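RNA was sequenced from full-thickness pieces of mouse uterine horn, about 2 mm long and taken from the middle of the horn, in animals of the C3H strain collected at estrus. The labels describe 18 samples from 10 animals. In 3 animals the left horn had been injured by surgery during diestrus, and in 3 others during estrus, about 1 month earlier. The right horn of these animals was left uninjured, so that each phase of injury has 3 injured and 3 uninjured samples. The remaining 6 samples are from 4 animals without surgery, 4 from left and 2 from right horns. The title of the series names the question as the effect of injury in diestrus on embryo spacing and on the Cox-2 pathway, the pathway of the prostaglandin-forming enzyme encoded by Ptgs2.

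Only 2 of the 18 libraries are analysed here. The table names its columns by an animal code and a side. Of its 10 codes, 8 have a left and a right horn and 2 have a left horn alone, and in the labels the animals with a left horn alone are 2 untreated ones. The other 16 columns match no title and were not used, so none of the 9 comparisons planned between injured, uninjured and untreated horns was made, and nothing below bears on the effect of injury. What follows is the expression of the untreated left horn at estrus in 2 animals, with the difference between the animals as its error. The libraries held 68178389 and 60588346 counts and are called the deeper and the shallower library. A level of at least 1 CPM, the count scaled to the total of the library, was present in both libraries for 14054 of 27998 genes. Levels are given as TPM, which also takes account of gene length, as mean ± SD of the 2 animals (n = 2).

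Some of the genes known to be induced by oestrogen in the uterus were among the most abundant. The 23 measured members of this list, fixed before the data were examined, held 3.22% ± 0.33 (SD, n = 2) of all counts, and 22 of them reached 1 CPM in both libraries. Sprr2f, a small proline-rich protein of the luminal epithelium (ENSMUSG00000050635, chromosome 3, 92365187 to 92366442, GRCm38), ranked 2 among all genes at 17366 ± 1443 TPM (SD, n = 2). Lcn2, an iron-binding lipocalin (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), stood at 6114 ± 1560 TPM. Complement C3 (ENSMUSG00000024164, chromosome 17, 57203970 to 57228136) stood at 5329.7 ± 140.3 TPM and lactoferrin, Ltf (ENSMUSG00000032496, chromosome 9, 111019271 to 111042767), at 5095 ± 973 TPM. Clca1 reached 3156 ± 303 TPM. Other members were far lower, such as Greb1 at 13.5 ± 4.7 TPM and Igf1 at 13.4 ± 0.6 TPM, which ranked 8415 and 8471 among all genes. Olfm4 was the member below 1 CPM, with 12 and 32 counts. Members of the Sprr2 family are near-identical in sequence, so the division of reads among Sprr2a1, Sprr2a2, Sprr2a3, Sprr2b, Sprr2d, Sprr2e and Sprr2f is uncertain.

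The progesterone-induced list held a far smaller share, 0.0499% ± 0.0024 of counts, and 17 of its 22 members reached 1 CPM. By mean its highest members were the transcription factors Gata2 at 71.99 ± 3.87 TPM and Nr2f2 at 58.76 ± 2.91 TPM, but Alox15, a lipoxygenase gene, lay above both in the shallower library, at 94.6 TPM. Areg, an epidermal growth factor family ligand, had 14 and 34 counts, and Il13ra2 had 2 and 3 counts. A share depends on the genes chosen for a list, so those of the oestrogen-induced and progesterone-induced lists do not compare the hormones. Among steroid receptors, Esr1, the oestrogen receptor alpha, stood at 80.2 ± 5.8 TPM, Pgr, the progesterone receptor, at 27.9 ± 3.3 TPM and Ar, the androgen receptor, at 22.77 ± 0.03 TPM. The ratio of Esr1 to Pgr was 2.88 ± 0.14. Esr2, the oestrogen receptor beta, was near the floor, with 14 and 16 counts. The list of steroid receptors and steroid metabolism held 0.165% ± 0.008 of counts, with 19 of 23 members at 1 CPM or more. Cyp19a1, the aromatase gene, had no count in either library, which allows up to 0.0440 CPM in the deeper and 0.0495 CPM in the shallower library at a floor of 3 counts, or 0.0880 and 0.0990 CPM if each fragment gave 2 counts. The floor covers counting error only.

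**Figure D1:**
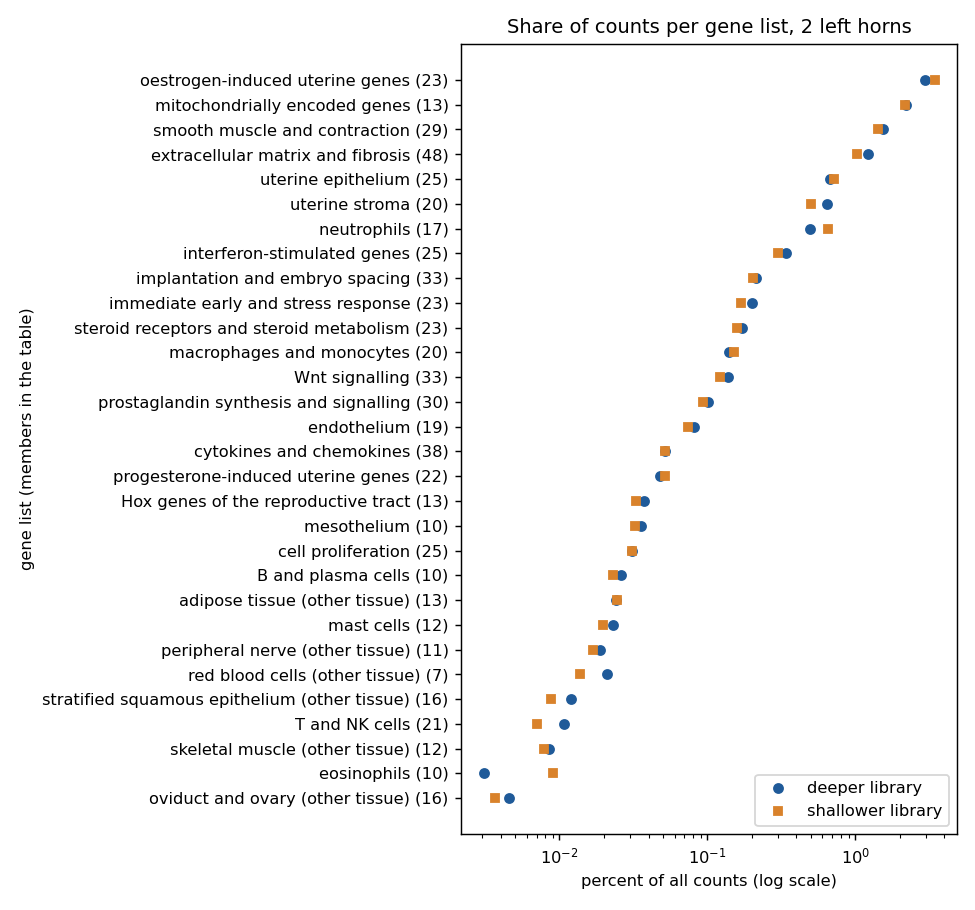
Share of all counts held by each of the 30 gene lists in 2 untreated left uterine horns. The x axis is the percent of counts on a log scale, circles are the deeper and squares the shallower library, and the number of measured members stands beside each list. The oestrogen-induced list lies at 2.98% and 3.45%.

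Genes of prostaglandin synthesis and signalling were present at moderate levels, and 25 of the 30 measured members reached 1 CPM in both libraries. Ptgs2, which encodes the inducible cyclooxygenase Cox-2 (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227), stood at 67.6 ± 35.5 TPM, from 9336 and 3866 counts. Ptgs1, which encodes the constitutive cyclooxygenase Cox-1 (ENSMUSG00000047250, chromosome 2, 36230426 to 36252272), stood at 17.33 ± 8.55 TPM, from 1997 and 871 counts. Ptgs2 exceeded Ptgs1 by 3.96-fold in the deeper and 3.76-fold in the shallower library, on the log2 scale by 1.95 ± 0.05. Both genes were about 2-fold apart between the animals, by 1.09 log2 units for Ptgs2 and 1.01 for Ptgs1, both higher in the deeper library. No test was run, since an exact two-sided test over 2 animals cannot give a p below 0.5.

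Of the terminal enzymes, Ptgis, the prostacyclin synthase, stood at 138.4 ± 8.7 TPM and Ptges3, a prostaglandin E synthase that is also a chaperone, at 166.5 ± 6.7 TPM. Ptges, the inducible prostaglandin E synthase, stood at 8.26 ± 4.24 TPM, Hpgds, a prostaglandin D synthase, at 15.6 TPM in the deeper and 6.45 TPM in the shallower library, and Tbxas1, the thromboxane synthase, at 2.39 ± 0.33 TPM. Akr1b3, an aldo-keto reductase with prostaglandin F synthase activity, stood at 24.7 ± 7.4 TPM. Pla2g4a, the cytosolic phospholipase that releases arachidonic acid, was at nearly the same level in both animals, 39.24 ± 0.10 TPM. Hpgd, which degrades prostaglandins, stood at 75.5 ± 2.4 TPM, above both cyclooxygenases in mean, although Ptgs2 in the deeper library was higher at 92.7 TPM. Among the receptors, Ptger4 at 24.5 ± 1.7 TPM and Ptger1 at 19.68 ± 0.26 TPM were the highest. Ptgir stood at 5.13 ± 1.13 TPM, Ptger3 at 4.55 ± 0.60 TPM and Ptgfr, the receptor of prostaglandin F, at 2.22 ± 0.03 TPM. Ptger2 differed between the animals, with 175 and 45 counts. The list held 0.0974% ± 0.0054 of counts.

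**Figure D2:**
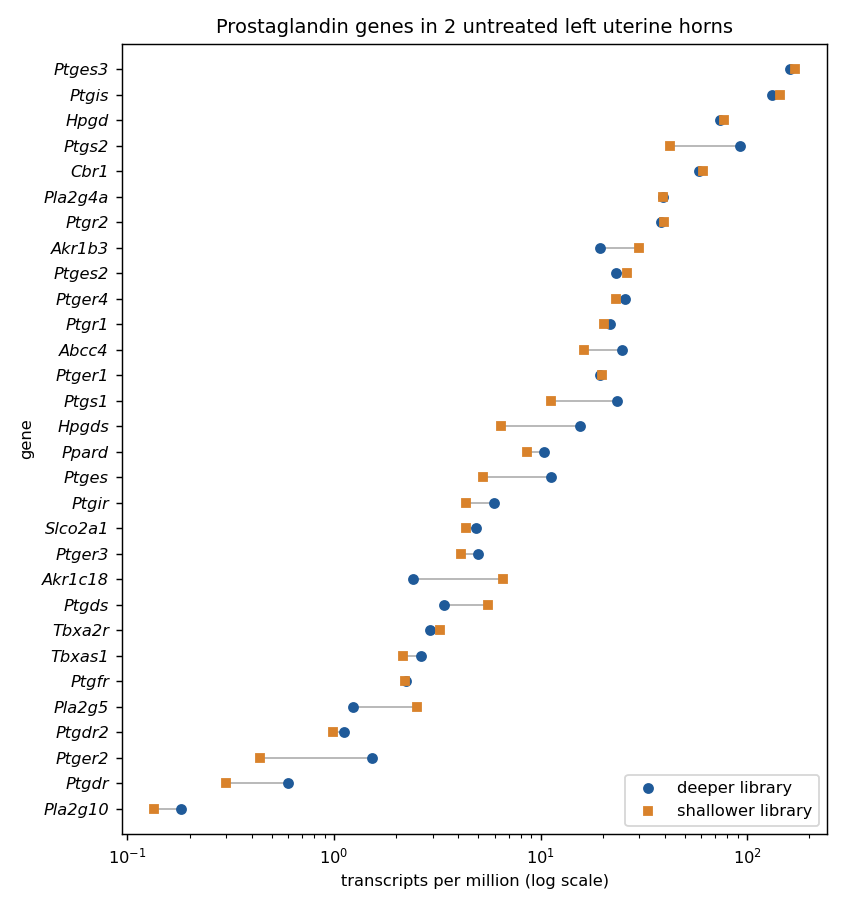
Level of each measured gene of prostaglandin synthesis and signalling in 2 untreated left uterine horns. The x axis is TPM on a log scale, circles are the deeper and squares the shallower library, and the grey line joins the values of a gene. Ptgs2 lies at 92.7 and 42.5 TPM and Ptgs1 at 23.4 and 11.3 TPM.

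Of 33 genes linked to implantation and embryo spacing, 28 reached 1 CPM in both libraries. Muc1, a mucin of the luminal surface, led at 565.6 ± 71.4 TPM, followed by Il6st, the shared receptor subunit for leukaemia inhibitory factor, at 153.1 ± 4.9 TPM. Lif itself stood at 30.3 ± 11.2 TPM and Lpar3, the lysophosphatidic acid receptor whose loss disturbs embryo spacing in mice, at 6.58 ± 1.36 TPM. The homeobox genes Hoxa10 and Hoxa11 stood at 82.1 ± 9.5 and 58.9 ± 6.5 TPM. Prss28, a protease of the glands, had 0 counts in both libraries, and its relative Prss29 had 0 and 2. The list held 0.208% ± 0.007 of counts. In the list of Hox genes Hoxd10 was highest at 117.7 ± 8.0 TPM, while Hoxa13 and Hoxd13 had no count in either library. That list held 0.0350% ± 0.0028 of counts. The Wnt list held 0.130% ± 0.011 of counts, led by Rspo3, a secreted enhancer of Wnt signalling, at 174.8 ± 8.0 TPM.

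Smooth muscle and contraction genes held 1.49% ± 0.08 of counts, led by Tagln at 6508 ± 173 TPM and by Myl9 and Acta2 at 2724 ± 167 and 2412 ± 168 TPM. The oxytocin receptor gene Oxtr stood at 16.2 ± 2.5 TPM and Gja1, the gap junction gene of the myometrium, at 36.6 ± 1.8 TPM. Extracellular matrix genes held 1.12% ± 0.14 of counts, with Sparc at 962 ± 105 TPM, the metalloproteinase Mmp11 at 741 ± 71 TPM and Col1a1 at 386 ± 55 TPM. Epithelial genes held 0.692% ± 0.031, led by Wfdc2 at 1426 ± 124 TPM and the keratin Krt8 at 1314 ± 131 TPM. Stromal genes held 0.576% ± 0.101, led by decorin, Dcn, at 1032 ± 212 TPM. Endothelial genes held 0.0777% ± 0.0058, with Sox17 at 77.4 ± 0.4 TPM, and mesothelial genes 0.0342% ± 0.0023.

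Markers of several leukocyte types were present, in a table without immunoglobulin or T cell receptor constant genes. The macrophage and monocyte list held 0.146% ± 0.008 of counts, all 20 members reached 1 CPM, and Cd14 led at 730 ± 212 TPM, followed by Lyz2 at 433 ± 29 TPM. Cd14 differed by -0.64 log2 units, deeper minus shallower library, while the median of the list differed by 0.10. The share was 0.141% in the deeper and 0.152% in the shallower library, so it need not follow the other members. The neutrophil list held 0.575% ± 0.116, but 0.00249% ± 0.00013 without Ltf, which oestrogen also induces in the epithelium. After Ltf its highest members were Retnlg at 45.5 ± 6.5 TPM and Csf3r at 5.15 ± 0.03 TPM, and S100a9 had 40 counts in each library. The mast cell list held 0.0214% ± 0.0024, with the mast cell protease Mcpt4 at 33.5 ± 12.2 TPM. Its highest member was Gata2, which the progesterone-induced list also holds. The T and NK cell list held 0.00887% ± 0.00254 and the B and plasma cell list 0.0247% ± 0.0022. Of the latter, 10 of 17 members were in the table, and Txndc5, an endoplasmic reticulum gene that other cells also express, held most of the counts. Without it the share was 0.00547% ± 0.00277. Jchain, which joins secreted antibody chains, had 3842 and 1254 counts. The eosinophil list held 0.00603% ± 0.00418, set mostly by Alox15, which the progesterone-induced list also holds and which had 1205 and 4612 counts. Cytokine and chemokine genes held 0.0516% ± 0.0004, led by Ccl8 at 291 ± 64 TPM and Cxcl14 at 278 ± 11 TPM. Interferon-stimulated genes held 0.318% ± 0.029, and all 25 measured members reached 1 CPM, led by Ifi27l2a at 1912 ± 212 TPM.

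Among the other lists, proliferation genes held 0.0308% of counts in the deeper and 0.0309% in the shallower library, with Mki67 at 5.30 ± 0.73 TPM. Immediate early and stress genes held 0.184% ± 0.022, led by Ier3 at 719 ± 159 TPM. Mitochondrially encoded genes held 2.19% ± 0.02, but 6 of the 13 genes lay far below the other 7, from a cause that stayed open. If reads of these 6 genes were lost in library preparation or counting, the share is too low, which its SD does not cover. Ranks among all genes, such as that of Sprr2f, could then be too high. The lists of other tissues held between 0.00411% and 0.0241% of counts, and some of their members were well above 1 CPM. The oviduct and ovary list held 0.00411% ± 0.00060 and skeletal muscle genes 0.00817% ± 0.00043, led by Acta1 at 91.4 ± 16.3 TPM. Of the 12 skeletal muscle genes only 6 reached 1 CPM in both libraries, and 4 had no count in either. Red blood cell genes held 0.0173% ± 0.0051, led by the globin genes Hba-a1 at 332 ± 104 TPM and Hbb-bs at 294 ± 88 TPM. Peripheral nerve genes held 0.0178% ± 0.0013, led by Pmp22 at 94.33 ± 9.97 TPM, and stratified squamous genes 0.0103% ± 0.0022, in which Sprr1a at 278 ± 78 TPM held most of the counts and Krt5 had 8 counts in each library. The adipose list held 0.0241% ± 0.0003, in which Pnpla2, also expressed outside fat, led at 120.9 ± 0.1 TPM, and Adipoq had 0 and 4 counts.

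The biological coefficient of variation between the animals, from edgeR, was 0.145 over 14329 genes. Each animal gave a single library, so this value also holds differences of tissue piece and library preparation. It was not adjusted for the case that each fragment gave 2 counts. Of these genes 275, or 1.92%, were over 2-fold apart, 151 higher in the deeper and 124 higher in the shallower library. Gpr179, an orphan receptor gene (ENSMUSG00000070337, chromosome 11, 97332109 to 97352077), was 9.66-fold higher in the deeper library, from 22913 and 2088 counts. Gzmb, a granzyme of cytotoxic cells, was 5.75-fold and Sprr2b 3.32-fold higher in the deeper library. Aoc1, which degrades diamines, was 5.42-fold, Spink12 5.38-fold and Alox15 4.34-fold higher in the shallower library. These are differences between 2 libraries and have no replicate check.

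Lists of whole cell types also lay apart between the 2 animals. The median gene of the stromal list was 0.31 log2 units higher in the deeper library, with 19 of 20 members on that side, and the endothelial median was 0.26 and the extracellular matrix median 0.22 higher. Smooth muscle genes were 0.15 higher in median, with 21 of 27 members on that side. The B and plasma cell list had a median of 0.68, with 4 of 6 members on that side and a standard error of 0.42, and the oviduct and ovary list one of 0.47, with 4 of 5 members on that side and a standard error of 0.24. Mast cell genes were 0.31, mesothelial genes 0.28 and T and NK cell genes 0.28 (standard error 0.23) higher in median. Hba-a1, Hbb-bs, Hbb-bt and Alas2 of the red blood cell list were 0.58 to 0.68 higher. Immediate early and stress genes were 0.32 higher in the deeper library in median, Wnt genes 0.24 and interferon-stimulated genes 0.19 higher. Implantation and embryo spacing genes were 0.16 higher in median (standard error 0.12), with 20 of 28 members on that side. Hox genes were 0.18 and macrophage genes 0.10 higher (standard errors 0.07 and 0.10). Epithelial and oestrogen-induced genes went the other way, by -0.11 and -0.14 log2 units, with 14 of 23 and 16 of 22 members higher in the shallower library. The standard errors of these medians were 0.08 and 0.15, the latter larger than the median in size. Each of these list medians lay outside the central 95% of 10000 random lists matched on expression. Of 27 lists with at least 5 members in the fit, 17 did so, 15 on the side of the deeper library and 2 on the other, where chance gives 5%. The lists share some genes and genes of a list vary together, so this describes these libraries only. The prostaglandin list had a median of -0.01, inside the range of the random lists, but its members went both ways. Of 27 members 7 were over 2-fold apart, with Ptgs1, Ptgs2, Ptges, Hpgds and Ptger2 higher in the deeper and Akr1c18 and Pla2g5 higher in the shallower library. The 1.92% of all genes over 2-fold apart is not matched to these members in level. By mean log2 CPM, Ptgs2 lay at 6.55, Hpgds at 4.39, Ptgs1 at 4.36 and Ptges at 3.30. Few genes of such levels were that far apart: 8 of 3125 at 6 to 8, 37 of 5454 at 4 to 6 and 59 of 3055 at 2 to 4. Ptger2, Akr1c18 and Pla2g5 had lower means of 1.65, 1.77 and 1.77 CPM. Below 2 log2 CPM, 169 of 2152 genes were over 2-fold apart.

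**Figure D3:**
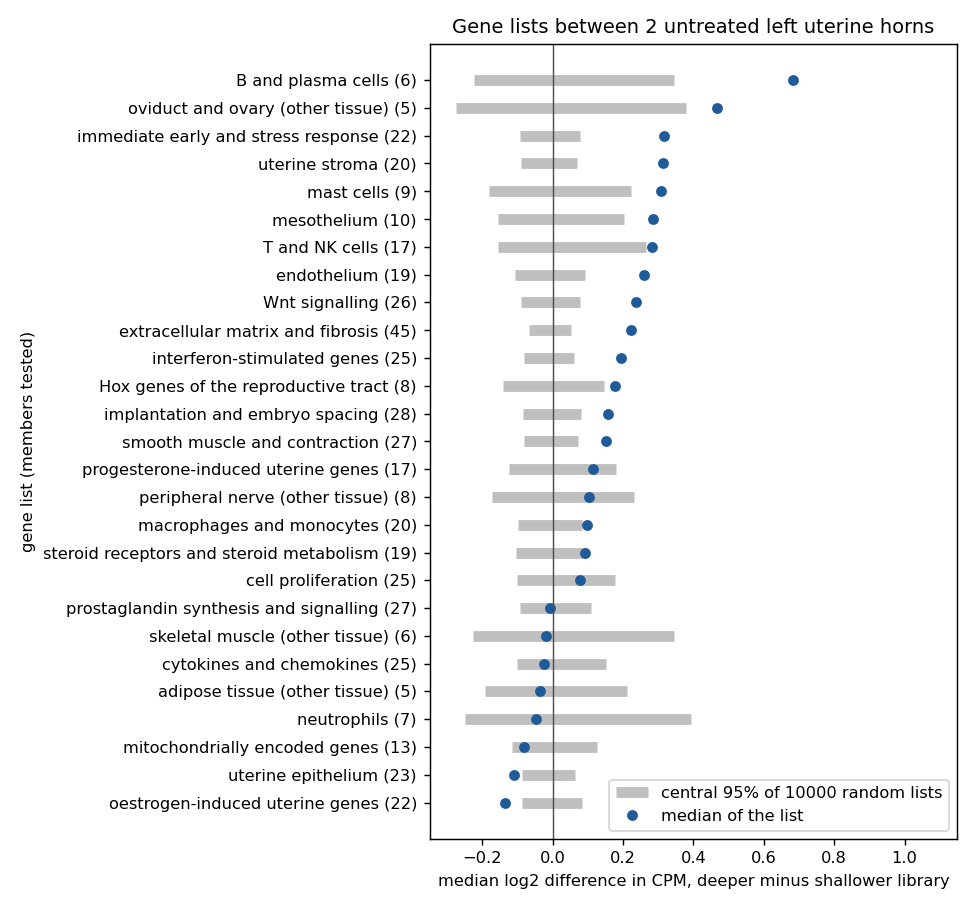
Median log2 difference in CPM between the deeper and the shallower untreated left-horn library for 27 gene lists, with the number of members in brackets. Points are list medians and grey bars the central 95% of 10000 random lists matched on expression. The stromal list lies at 0.31 and the oestrogen-induced list at -0.14, both outside their bars.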

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

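Alternatives to the values reported were all chosen after the data were seen, since the planned ones belong to comparisons that were not made and were not run. No paired analysis was possible because the groups to be compared could not be assigned to columns: the names pair the left and right horns of 8 animals without saying which were injured, and sides were not compared over mixed groups. The biological coefficient of variation of 0.145 was 0.158 without a low-count filter and 0.117 at a mean of at least 10 CPM, and 0.145 with median-of-ratios factors or total counts alone. Genes in both libraries numbered 15033 at 0.5 CPM and 18990 at any count. The log2 ratio of Ptgs2 to Ptgs1 fell from 1.95 to 1.55 when the longest annotated transcript gave the gene length, through the length of Ptgs2, and kept its direction. The share of counts of the oestrogen-induced list was 2.86% without the Sprr2 genes and 3.29% without mitochondrial genes. Leaving out a library is no test of stability here, since a single library of 2 always lies within 1 SD of their mean. The single libraries gave 92.7 and 42.5 TPM for Ptgs2, and 23.4 and 11.3 TPM for Ptgs1. Depth limits genes of a few counts, such as Il13ra2 and Krt5.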

Other observations

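Apart from the fixed lists, the most abundant transcripts of the untreated left horn included the secreted protein gene Prap1, at 5966 TPM in the deeper and 4622 TPM in the shallower library, a level close to that of lactoferrin. Among genes of antigen presentation by class I molecules, picked after their values were seen and not tested as a group, some differed between the 2 animals. B2m, their shared light chain, had 3243 TPM in the deeper and 5868 TPM in the shallower library, H2-K1 650.0 and 1546 TPM, and H2-D1 419.7 and 766.7 TPM. H2-Q7 was 1.71-fold, H2-Q4 1.51-fold and H2-T22 1.17-fold higher in the shallower library. H2-T23 was higher in the deeper library, at 403.5 and 348.3 TPM.

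Of the tests that follow, that on the share of epithelium was chosen after the result was seen. Of the 13 mitochondrially encoded protein genes, 6 lay far below the other 7, as mt-Co2 with 1874 counts in the deeper library against 683308 for mt-Co1. As the whole cause, that short transcripts were lost in library preparation is argued against: 3 of the 6 low genes, of 681 to 784 bases, are longer than the high gene mt-Nd6, and 110 nuclear genes of these lengths had a 90th percentile of TPM 0.39 log2 units (bootstrap SE 0.41) above that of 1705 genes of 957 to 1824 bases. Yet mt-Nd6 lies on the other strand, under an unknown strand setting, and the other 6 high genes are each longer than every low gene. For the 3 low genes shorter than mt-Nd6, loss of short transcripts stays open. For these, 17 nuclear genes of 204 to 348 bases gave -3.92 with a bootstrap SE of 1.45. The nuclear comparisons are between different genes, so differences in their true levels could hide part of a loss. Another candidate explanation is reads shared with near-identical nuclear copies, which counting then drops or divides: an annotated nuclear copy at 98% identity or more over at least 90% of the transcript exists for 5 of the 6 low genes and 0 of the 7 high genes. The split depends on that limit, since the high gene mt-Co1 has a copy at 97.6% identity, just under it. The high genes mt-Nd6 and mt-Cytb have copies at 93.6% and 92.9%. Sharing of reads stays open too because mt-Atp8 has no such annotated copy and the genome itself was not searched. No biological explanation was tested.

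The stromal and epithelial lists lay 0.42 log2 units apart between the 2 untreated animals. A bias with gene length and GC content is argued against as the whole cause, since the gap was still 0.40 after their trend was removed, a trend that held 2.48% of the variance between the libraries. Stromal, endothelial and smooth muscle genes lay on one side. So did mast cell, T and NK cell, B and plasma cell, and oviduct and ovary genes, and macrophage genes by 0.10. Neutrophil genes at -0.05, adipose genes at -0.04 and skeletal muscle genes at -0.02 lay inside the ranges of their random lists. A smaller share of epithelium in the piece that gave the deeper library may account for the gap. It cannot be told apart from changes within the cell types, because the stromal median exceeded the smooth muscle median by 0.16 with a standard error of 0.08, which is over 2 standard errors but under the bound of 0.2 log2 units, itself set after the values were seen, and genes of a list vary together, so that this error is too small. The design has no group to set against it, so no biological explanation was tested.

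The genes over 2-fold apart between the animals might reflect variants that differ between them and act on neighbouring genes. The set had no excess of neighbours over the range of random sets, but the test cannot exclude linked variants as the cause of the set. Of 273 such genes with coordinates, 58 had another within 0.5 Mb under a different name stem, while 1000 random sets matched on expression had a median of 56, with a central 95% of 39 to 72. The test was not tried on simulated linked variants. In the fit, 169 of the 275 genes over 2-fold apart had a mean below 2 log2 CPM, where the spread was widest. Single loci are not excluded by a test on the set, that of Gpr179 was not tested further, and no other biological explanation was tested.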
